A study of Mus musculus with 4 samples.

How the data were processed

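Total RNA was sequenced from CD19 B cells of the spleen of female F1 mice, offspring of a C57BL/6 mother and a CAST/EiJ father, at 67 days of age. Per the labels, 300 ng of RNA went into each library, ribosomal RNA was depleted, the libraries keep strand, and ERCC spike-in RNAs were added. The 4 libraries form 1 group and are numbered in the labels as biological replicates 1 to 4. The labels list them as separate biosamples under 1 strain record and do not spell out separate animals, so p-values measure the spread between these samples, part of which may be technical.

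Each library has a gene table and a pair of transcript tables. The deposited gene table gives expected counts per gene, which need not be whole, and TPM, per the file headers. Expected counts are reads assigned by a model that splits reads between similar transcripts. The file headers also name an effective length. TPM values are by definition counts divided by effective length and scaled to a common total within the library. The deposited values include spike-ins, phiX and numbered rows with no gene name. One transcript table has the column layout of RSEM and comes from a transcriptome alignment, the other has the layout of kallisto and comes directly from reads, per the deposited descriptions. They are called the RSEM-layout and the kallisto-layout table here. The build is mm10 with GENCODE M21 annotation, per the deposited descriptions. The aligner, the quantifiers and their versions are not given in the sources used here. All 55536 Ensembl gene rows matched GENCODE M21, from which symbols, coordinates and gene types were taken. Coordinates are 1-based on mm10.

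Total expected counts were 19033466, 16891960, 16882676 and 15299860 in replicates 1 to 4, and spike-ins took 0.270% ± 0.0126 (SD, n = 4) of them. The 26248 numbered rows with no gene name held at most 10 expected counts in a library. They stayed out of library sizes and tests. Where genes had the same symbol, the one of highest mean TPM was used, except that both Nnt entries are given. The list members Ahsp, Ighg2a, Rn45s and Rn7sl1 are absent from the annotation.

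Expected gene counts were rounded to whole numbers for count tests. Genes that varied between libraries were found with edgeR 4.0.16 in R 4.3.3, by an intercept-only quasi-likelihood fit with TMM scaling, robust estimation and genes of mean CPM of at least 1. The ratio of each gene's quasi-likelihood dispersion to the abundance trend was tested on the F distribution with Benjamini-Hochberg adjustment at 0.05. Levels were tested with limma 3.58.1 on log2(TPM + 0.1), one-sided each way against 1 TPM, over the 22973 genes with a nonzero value. Transcript tables were compared within library with limma on log2(TPM + 0.1), at an adjusted p of 0.05 and an absolute log2 ratio of at least 1, for transcripts of at least 1 TPM in either table. Differences between the medians of marker lists were tested by exact two-sided sign-flip permutation, which with 4 libraries cannot go below 0.13. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the rest, and DESeq2 1.42.0 for an alternative.

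The 32 gene lists and the rule for named genes were fixed before the data were examined. The rule takes the 25 protein-coding or immunoglobulin constant genes of highest mean TPM, the 4 highest and 2 lowest members of each list with every member past the variability threshold, the 25 genes of smallest p in that test, the 5 leading V genes per locus, isoform list genes of at least 1 TPM, and all members of the immunoglobulin, sex and strain lists. The ranking of the 25 most abundant genes left out mitochondrial, spike-in, small nucleolar and structured RNA genes. The rule gave 260 genes. The median dispersion ratio of each list was ranked among 10000 random lists of equal size, matched on mean expression through the 50 nearest genes. The share of each gene's sequence, in overlapping pieces of a fixed length, that also occurs in another gene was computed from the annotated transcripts, since reads from such sequence can be split between copies. The V gene CV covers V genes of at least 1% of their locus, and the V gene chi-square covers genes of at least 20 counts. The fixed plan did not name either minimum.

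The tests were tested on simulated data. With counts for 12778 genes and none changed, the variability test called 0 genes. Every gene was drawn at the abundance trend of the dispersion, with no spread of dispersion between genes. The 0 calls therefore do not give the rate of false calls in the real data, where dispersion differs between genes. With 50 genes per fold size changed in 1 library, the variability test recovered 62% at 2-fold, 86% at 4-fold, 96% at 8-fold and 92% at 16-fold, and called 5 unchanged genes. In the level test, 0.01% of the genes called above 1 TPM had a true level below it, over 21997 genes. These genes were also drawn at the trend of the dispersion, so the same limit holds. The transcript test recovered 99% of the transcripts shifted by 4-fold among 35540 and called 0 others. Its simulated tables differed by a small random error with no offset, so an unshifted transcript could hardly reach the ratio threshold. The 0 other calls therefore do not give the rate of false calls between the real tables, which can differ in TPM scale. Of 200 random lists of 10 genes, 6.5% ranked above the 95th percentile.

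Alternatives covered pseudocounts, filters, other scalings, DESeq2 dispersion outliers, the kallisto-layout table, TPM rescaled without small and mitochondrial RNA, and leaving out each replicate. Another 2 alternatives were added after seeing the data, namely leaving out genes that share sequence and a lower V gene minimum. Splits of the samples were not drawn, since there is 1 group. Allele-specific expression was not analysed here.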

Results

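Total RNA-seq of splenic CD19 B cells, the antibody-producing lymphocytes selected by a surface protein that marks the B lineage, was available from 4 replicate libraries of female C57BL/6 by CAST/EiJ F1 mice. Total expected counts were 19033466, 16891960, 16882676 and 15299860 in replicates 1 to 4, and between 19213 and 19760 genes had a count. The labels name no contrast, so gene levels, their spread between libraries and differences between gene lists within libraries were measured. No pair of libraries was a duplicate, with a chi-square per degree of freedom of their counts from 6.50 to 16.3 against counting error alone, which separate samples exceed. Across genes, which are not independent replicates, the lowest Pearson correlation of log2(TPM + 1) between a pair of libraries was 0.991.

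The most abundant messenger RNAs included those of MHC class II, immunoglobulin constant and ribosomal protein genes. Mitochondrial genes, which summed to 63801 ± 3429 TPM (SD, n = 4), were left out of this ranking. Cd74 (mm10 chromosome 18, 60803848 to 60812652), the invariant chain of MHC class II, led the other protein-coding genes at 5833 ± 412 TPM (SD, n = 4). The ribosomal protein gene Rps27 followed at 3514 TPM. Igkc, the kappa constant gene, stood at 2811 ± 158 TPM, Ighm at 2505 ± 121 TPM and the class II gene H2-Ab1 at 2108 ± 113 TPM. The elongation factor gene Eef1a1 stood at 2782 ± 135 TPM and the actin gene Actb at 2758 ± 196 TPM. The small structured RNAs Rn7s1, Rn7s2 and Rn7sk took 35.5% ± 0.645 (SD, n = 4) of all TPM in the gene table. Rn7s1 and Rn7s2 share all of their sequence, so their separate levels are uncertain. In the kallisto-layout table Rn7s1 and Rn7s2 each stood at 80836 ± 66947 TPM and Rn7sk at 59664 ± 35829 TPM, with a far larger spread. Of 22973 genes tested with limma, 11314 lay above 1 TPM and 9376 below it, and 2283 passed neither test. Of those above, 9536 were protein-coding. Leaving small and mitochondrial RNA out of the total raised TPM by a factor of 1.86 to 1.92 in the 4 libraries, with Cd74 at 11054 TPM.

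The libraries were compared with marker lists to see which cells they hold. All 26 B lineage markers lay above 1 TPM, also when adjusted over the list alone, among them Cd37 at 618 ± 34.3, Cd79b at 610 ± 40.7, Cd79a at 602 ± 29.2 and Cd19 at 430 ± 16.8 TPM (SD, n = 4). Cd79a and Cd79b encode the signalling chains of the B cell receptor. The median of the B lineage list exceeded that of the T cell list by 7.79 ± 0.434 (SD, n = 4) on the log2(TPM + 0.1) scale, in 4 of 4 libraries. The exact sign-flip permutation test gave p = 0.13, the smallest two-sided value that 4 libraries allow. The difference from the monocyte and macrophage list was 7.11 ± 1.11, from the NK cell list 8.06 ± 0.683, from the neutrophil list 8.54 ± 0.326 and from the dendritic cell list 9.01 ± 0.135. It was 9.19 ± 0.564 for the erythroid, 10.21 ± 0.487 for the megakaryocyte and platelet and 10.45 ± 0.255 for the stroma and endothelium list. With members of at least 0.1 TPM alone, the erythroid difference was 3.86 ± 1.19 and the megakaryocyte and platelet difference 8.22 ± 1.08. Among other cell types, 3 of 19 T cell markers lay above 1 TPM (1 adjusted over the list alone), as did 6 of 20 monocyte and macrophage, 5 of 13 erythroid and 0 of 17 stromal markers. Of the remaining lists, 1 of 11 NK cell, 2 of 14 neutrophil, 1 of 12 dendritic cell and 1 of 10 megakaryocyte markers did, and apart from T cells the counts adjusted over the list alone were the same. The T cell kinase gene Lck stood at 9.93 ± 2.42 TPM and the macrophage receptor gene Csf1r at 2.52 ± 1.66 TPM.

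**Figure D1:**
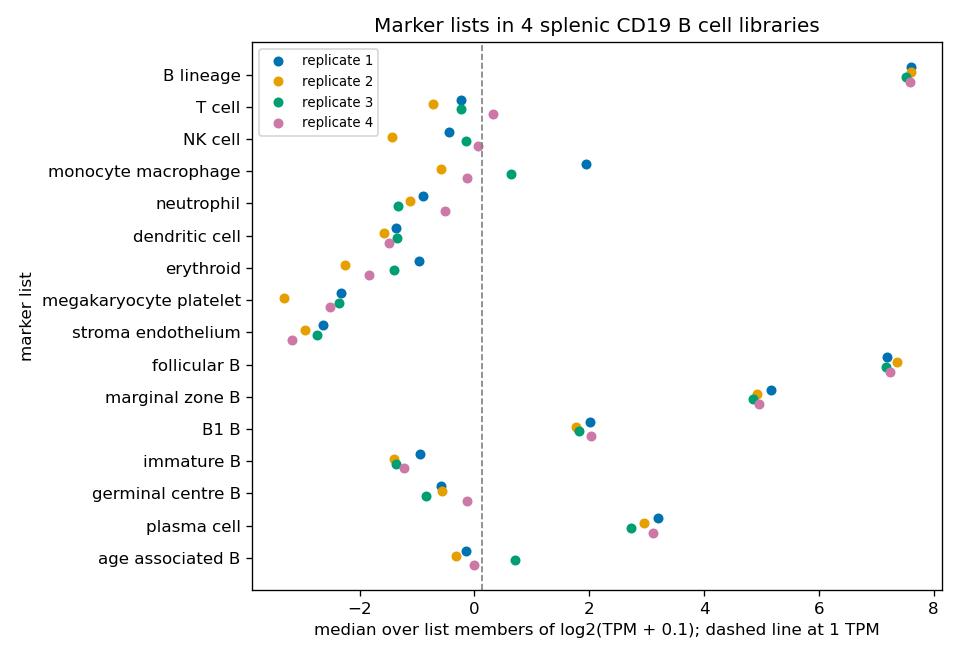
Median log2(TPM + 0.1) over the members of each cell type and B subset list (x axis), with 1 point per library and a dashed line at 1 TPM. The B lineage list lies near 7.58 in all 4 libraries, and the monocyte and macrophage list spreads most between them, with replicate 1 highest.

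Among B cell subsets, follicular markers had the highest median, 7.24 ± 0.08 (SD, n = 4) on the log2(TPM + 0.1) scale. All 10 lay above 1 TPM, with Klf2 at 988 ± 229, Ighd at 700.3 ± 11.96 and Ccr7 at 202 ± 29.5 TPM. The follicular median exceeded the marginal zone median by 2.27 ± 0.176, the plasma cell median by 4.24 ± 0.212 and the B1 median by 5.33 ± 0.184, each in 4 of 4 libraries (exact sign-flip permutation p = 0.13). It exceeded the age-associated list by 7.18 ± 0.517, the germinal centre list by 7.77 ± 0.281 and the immature list by 8.47 ± 0.255, or by 5.64 ± 0.144 with members of at least 0.1 TPM alone. All 12 marginal zone markers lay above 1 TPM, led by Cr2, complement receptor 2, at 310.5 ± 14.7 TPM, a gene that follicular B cells also express. Of the plasma cell markers 11 of 12 lay above 1 TPM, with Irf4 at 176 ± 17.9 and Jchain at 24.5 ± 6.16, and Prdm1 stood at 2.17 ± 0.399 TPM. Lists for B1 cells (5 of 8), immature cells (4 of 11), germinal centre cells (3 of 11) and age-associated cells (2 of 7) held fewer members above 1 TPM. Differences between lists compare different genes, so they do not measure shares of cells. Counts above 1 TPM adjusted over the list alone were the same for every B subset list.

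Heavy chain constant RNA, as counted on the C57BL/6 reference, was almost entirely of the unswitched isotypes. Reads of CAST/EiJ constant genes were counted only where they align, and Ighg2a is absent from the annotation. Ighm and Ighd together made up 98.98% ± 0.336 (SD, n = 4) of heavy chain constant TPM, with Ighm at 77.3% ± 0.619 and Ighd at 21.6% ± 0.577. Ighm exceeded Ighd 3.57-fold, with a log2 ratio of 1.84 ± 0.0482 in 4 of 4 libraries (exact sign-flip permutation p = 0.13). Ighg3 reached 0.649% ± 0.197, and each of Ighg2b, Igha, Ighg2c and Ighg1 stayed under 0.2% in every library. Ighe was listed at 0 in all 4 libraries, which allows it a share of at most 0.0039% of heavy chain constant counts by counting error alone. Of 8 heavy chain constant genes 6 lay above 1 TPM, and all 5 light chain constant genes did, with the same counts adjusted over the list alone. Of light chain constant TPM, Igkc took 58.3% ± 0.815, Iglc2 18.6% ± 0.429, Iglc1 18.4% ± 0.389 and Iglc3 4.62% ± 0.234. By expected counts the Igkc share was 61.8%. Lambda V genes summed to 191 ± 13.6 TPM against 2244 ± 93.1 TPM for kappa V genes (SD, n = 4), a far smaller lambda part. Constant and V genes thus disagree on the part of lambda, so the constant shares do not settle kappa against lambda usage. The cause was not tested.

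**Figure D2:**
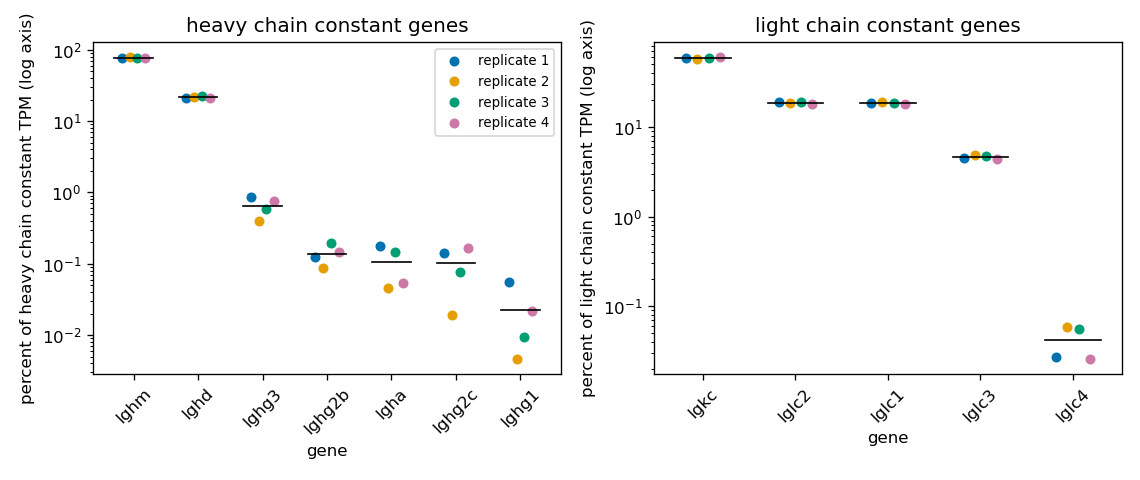
Percent of heavy chain (left) and light chain (right) constant TPM taken by each gene, on a log axis, with 1 point per library and a bar at the mean of 4. Ighm and Ighd average 77.3% and 21.6%, and Igkc averages 58.3%.

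V gene RNA was spread over many genes. The 5 leading heavy chain V genes took 21.9% ± 0.900 (SD, n = 4) of the V counts of their locus and the 5 leading kappa V genes 21.2% ± 0.459. In the gene table Ighv14-2 led the heavy chain locus at 5.25% ± 0.459 (chromosome 12, 113994469 to 113994898), followed by Ighv3-2 at 5.11% ± 0.299, while in the kallisto-layout table Ighv14-2 took 3.25%, below Ighv9-3 at 5.06%. Igkv1-110 led the kappa locus of the gene table at 5.57% ± 0.458 and Igkv10-96 followed at 4.67% ± 0.175, while in the kallisto-layout table they took 4.74% and 3.71%, below Igkv1-117 at 7.85%. Of the 3 lambda V genes, Iglv1 took 40.4% ± 2.21, Iglv3 29.8% ± 3.28 and Iglv2 29.8% ± 4.76 in the gene table, against 27.4%, 47.8% and 24.8% in the kallisto-layout table. The median CV between libraries was 9.94% over V genes of at least 1% of their locus. In the edgeR variability test 0 of 83 heavy, 0 of 86 kappa and 0 of 3 lambda V genes passed (0, 0 and 1 adjusted over the list alone), with median dispersion ratios of 0.807, 0.876 and 0.99. The chi-square per degree of freedom of V gene counts between libraries, which covers counting error alone, was 2.05, 2.23 and 5.91. The reference carries C57BL/6 V genes, so CAST/EiJ V genes were counted only where their reads align. Ighv4-2 took 4.26% in the gene table and 0.291% in the kallisto-layout table. Ighv3-2 and Ighv4-2, both among the 5 leading heavy chain V genes, are annotated as V pseudogenes. The heavy chain shares therefore do not measure the use of functional V genes alone.

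Genes of B cell function were abundant. All 12 MHC class II genes, all 24 B cell receptor signalling genes and all 17 survival and apoptosis genes lay above 1 TPM, as did 25 of 29 lineage transcription factors (26 adjusted over the list alone), with Pax5 at 325 ± 26.3 TPM. Toll-like receptor genes (11 of 17) and homing receptor genes (15 of 18) included Tlr9 at 51.7 ± 4.95, Sell at 202 ± 5.82 and S1pr1 at 112 ± 9.23 TPM. The interferon-stimulated list had 22 of 28 members above 1 TPM and the proliferation list 11 of 25, the same counts as adjusted over the list alone, with Pcna at 90.4 ± 12.3 and Cenpf at 0.253 ± 0.12 TPM. None of the members of the B lineage, MHC class II, B cell receptor, Toll-like receptor, interferon-stimulated and proliferation lists varied between libraries past the edgeR threshold. Adjusted over the list alone, 1 proliferation gene passed and no member of the other 5 lists. Over all genes tested, 907 passed at the unadjusted threshold and 241 were dispersion outliers in DESeq2. Xist, transcribed from the inactive X, stood at 106 ± 11.6 TPM, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty at 0.04 TPM or less on average in the gene table. In the kallisto-layout table Uty stood at 2.27 ± 0.699 and Kdm5d at 2.38 ± 0.666 TPM (SD, n = 4), with Ddx3y at 0.19 and Eif2s3y at 0.018 TPM. Both members of the reference strain list lay above 1 TPM and so did 11 of 13 structured RNAs and all 20 isoform list genes, with the same counts adjusted over the list alone. H2-Ea-ps, annotated as a polymorphic pseudogene because C57BL/6 lacks a working copy, stood at 520 ± 20.5 TPM (n = 4).

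Variability between libraries was tested gene by gene, because the replicates are the only contrast in the design. Of 12778 genes, 262 varied more than genes of similar abundance at an adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg). Heat shock genes, which encode chaperones, and immediate early genes, which respond quickly to stimulation, were among those called. Of 12 heat shock genes 8 varied (12 adjusted over the list alone), and of 22 immediate early genes tested 10 did (15 adjusted over the list alone). With libraries scaled on the spike-in total, 10 of these 18 calls were kept. Hspa1b (chromosome 17, 34956436 to 34959238) ranged 43.5-fold, with 4.96, 36.2, 201 and 216 TPM in replicates 1 to 4 (edgeR adjusted p = 1.2e-12). Hspa1a ranged 79.5-fold, Hsph1 4.09-fold, Fosb 4.37-fold, Fos 3.20-fold, Jun 2.68-fold and Dnajb1 2.28-fold, with their lowest TPM in replicate 1 and their highest in replicate 4. By TMM-scaled counts, which the calls use, Hspa1b and Dnajb1 were highest in replicate 3. Without replicate 1 the folds were 5.95 for Hspa1b, 8.04 for Hspa1a, 1.91 for Hsph1, 1.89 for Fosb, 1.83 for Fos, 1.76 for Jun and 1.79 for Dnajb1. Replicate 4 also held 11.1% of its counts in Gm26917 and Gm42418, chosen after their values were seen, against 8.85% to 9.30% in the others. Its mitochondrial share was 6.91% against 7.69% to 8.49%, and its small nuclear RNA summed to 51290 TPM against 72003 to 84848 TPM. The median dispersion ratios of the heat shock and immediate early lists exceeded those of all 10000 random lists matched on expression. So did those of the T cell, monocyte and macrophage, erythroid and marginal zone lists. The ribosomal protein, mitochondrial, replication histone and small nucleolar RNA genes did as well. Members of a list can change together in a library, which random lists do not reproduce, so the rank is a description. Hspa1a shares 48.4% and Hspa1b 49.7% of its sequence with another gene, and the summed counts of Hspa1a, Hspa1b and Hspa1l were still called (edgeR adjusted p = 6.5e-13). Of the stress genes, Cd69, Hsp90aa1, Hspd1, Junb and Klf6 lost their call without replicate 1, with edgeR adjusted p-values from 0.152 for Hspd1 to 0.851 for Cd69. Egr1, Egr2 and Junb lost it without replicate 2 (edgeR adjusted p of 0.593 for Egr1), Egr2 and Hspd1 without replicate 3 (0.264 for Egr2), and these 4 with Jund without replicate 4 (0.406 for Junb).

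**Figure D3:**
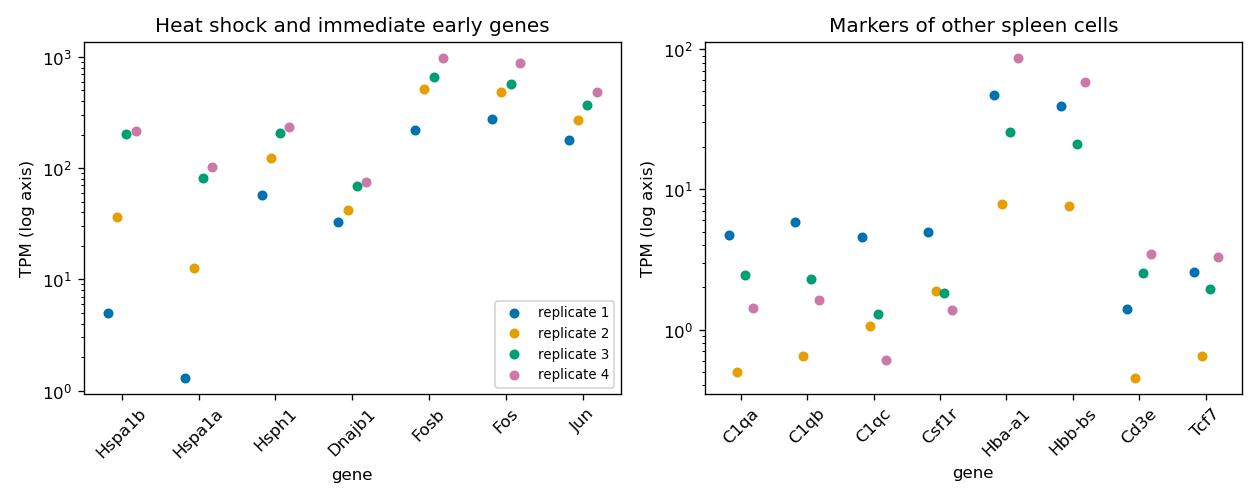
TPM of heat shock and immediate early genes (left) and of markers of other spleen cells (right) in each library, on log axes, with 1 point per library. Hspa1b lies at 4.96 TPM in replicate 1 and 216 TPM in replicate 4, and C1qb at 5.82 TPM in replicate 1 and 0.65 TPM in replicate 2.

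Markers of other spleen cells also varied. Of 14 monocyte and macrophage genes tested 9 varied (11 adjusted over the list alone). Csf1r was at 4.98 TPM in replicate 1 against 1.39 to 1.87 TPM in the others (edgeR adjusted p = 0.00011), and the complement gene C1qb ranged 8.95-fold (edgeR adjusted p = 0.0067). The fold of C1qb was 3.51 without replicate 1 and 3.57 without replicate 2. Of 11 T cell genes 2 varied (5 adjusted over the list alone), Cd3e and Tcf7, and of 5 erythroid genes 4 did (4 adjusted over the list alone). The alpha globin gene Hba-a1 ranged from 7.87 TPM in replicate 2 to 85.8 TPM in replicate 4 (edgeR adjusted p = 2.0e-07). This 10.9-fold range was 3.33-fold without replicate 2 and 5.94-fold without replicate 4. Among heavy chain constant genes 4 of 7 varied, namely Ighg1, Ighg2c, Ighg3 and Igha, while Ighm and Ighd did not pass, and 5 passed adjusted over the list alone. With kallisto-layout counts only 1 of these 7 genes passed. Of other lists, 2 survival genes (4 adjusted over the list alone), 2 lineage transcription factors (2), 1 follicular gene (1), 1 plasma cell gene (2), 1 structured RNA (5), 1 reference strain gene (1) and 0 homing receptor genes (3) passed. The reference strain gene was the Nnt entry of longer span, and the other Nnt entry moved in the opposite direction. Calls also ended for Klf2 without replicate 1 (edgeR adjusted p = 0.128) or 4 (0.194), Jchain without 2 (0.209) or 3 (0.16) and Nnt without 1 (0.992). They ended for Snhg1 without replicate 1 (0.956), 3 (0.137) or 4 (0.06), Pmaip1 without 1 (0.298) or 3 (0.279) and Bcl2a1d without 1 (0.744), 2 (0.109) or 4 (0.127). Without replicate 1, where the macrophage list was highest, all 9 macrophage genes lost their call, with edgeR adjusted p = 0.067 for Csf1r and 0.437 for C1qb. Their folds then ran from 1.35 for Csf1r to 5.97 for Axl, so a lost call does not mean that no difference was left. C1qa, C1qb and Mrc1 also lost their call without replicate 2 (0.084 for C1qb), and C1qc and Mrc1 without replicate 4 (0.08 for C1qc). Without replicate 2, Cd3e (edgeR adjusted p = 0.826), Tcf7 (0.996), Hbb-bt (0.883), Ighg3 (0.705) and Ighg2c (0.554) lost theirs. Cd3e also lost it without replicate 3 (0.055) or 4 (0.15), and Tcf7 (0.08) and Hbb-bt (0.127) without replicate 4. Ighg1 and Igha did too without replicate 2, 3 or 4, and Igha without replicate 1. Ighg1 still ranged 12.3-fold without replicate 3 or 4 and 6.38-fold without replicate 2. Igha ranged 4.03-fold without replicate 3 or 4, 3.29-fold without replicate 2 and 3.06-fold without replicate 1. None of the lists of light chain constant, NK cell, neutrophil and dendritic cell genes had a member past the edgeR threshold.

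The call depended on the fit. Without robust estimation 69 genes passed, and without replicate 4 129 did. Of the 262 genes, 134 share 50% or more of their sequence with another gene or are too short to search, against 647 of all 12778 tested. mt-Co2 (chromosome M, 7013 to 7696) had 10936 counts in replicate 1 and 2 in replicate 2, and 99.5% of its sequence also occurs in another gene.

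Spike-ins varied slightly less than genes of similar counts. The median SD of log2 level over 33 spike-ins was 0.132, against 0.156 for genes matched on mean count, a difference of -0.024. Without replicate 4 the difference was -0.0067 (spike-in spread minus gene spread).

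Isoforms were compared between the transcript tables, which share their reads and so measure the quantifiers. The leading transcript was the same for 6978 of 9653 genes with at least 1 TPM, or 72.3%, and for 15 of 20 isoform list genes. Ighm-202 made up 69.6% ± 1.64 of Ighm in the RSEM-layout table and 70.2% ± 1.43 in the other (SD, n = 4). Ptprc-207 led Ptprc at 40.0% ± 1.54 and 40.2% ± 7.17, and Ms4a1-201 led Ms4a1 at 81.5% ± 1.49 and 79.2% ± 1.49. The leading Ikzf1 transcript (ENSMUST00000076700.10) took 58.0% ± 4.59 in the RSEM-layout and 25.1% ± 0.937 in the kallisto-layout table, where Ikzf1-203 led at 32.1%. With limma, 13523 of 47338 transcripts differed between the tables at an adjusted p of 0.05 and 1 log2 unit, of which 10757 were higher in the kallisto-layout table. The ratios were not centred, so a difference in TPM scale between the tables enters this count and its direction. Cd74 stood at 5833 TPM in the gene table and 10410 TPM in the kallisto-layout table, and Rn7s1 at 143060 and 80836 TPM. Without replicate 1, 8874 transcripts differed.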

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

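All tests of explanations below were chosen after the result was seen, except the test of call counts under other scalings. Of 332 values tested for a library far from the other 3, 21 passed, against about 1 in 20 expected by chance. The number beside each is the gap to the nearest library divided by the whole range.

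Among lists, the medians of the B lineage (0.846, replicate 3 low), immediate early (0.876, replicate 4 high), reference strain defect (0.906, replicate 1 low), heavy chain constant (0.963, replicate 2 low) and structured RNA (0.871, replicate 1 low) lists had a library apart. Among genes, H2-K1 (0.940, replicate 4 high), Iglc2 (0.842, replicate 1 high), Sell (0.873, replicate 1 high), Tpt1 (0.934, replicate 2 low), Txndc5 (0.876, replicate 3 low) and Prdm1 (0.940, replicate 3 low) did. The other genes were mt-Co3 (0.879, replicate 4 low), Hist1h4n (0.924, replicate 4 low), Rpl7a-ps11 (1.0, replicate 4 high), Gm45062 (1.0, replicate 1 high), Nnt (0.922, replicate 1 low), Trbc2 (0.833, replicate 2 low), Tsix (0.851, replicate 4 high) and Ccl28 (0.867, replicate 2 high). The share of Igkv1-117 (0.947, replicate 3 low) and the leading isoform share of Lyn (0.897, replicate 4 low) completed the set. Both the Nnt value and the reference strain median used the Nnt entry of longer span, while the other Nnt entry was highest in replicate 1. Outside the comparisons, at least 35 counts fell on the phiX control in each library, and up to 10 expected counts on rows with no gene name.

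Heat shock and immediate early genes differed between libraries. All 18 called members share no more than 50% of their sequence with another gene, which argues against reads split between copies. In the test fixed beforehand, 10 of the 18 stayed called when libraries were scaled on the spike-in total, a value between the bounds set for and against scaling, so that test left it open, and the common BCV that genes were set against rose from 0.101 to 0.124. By size, 18 of 18 members ranged over the libraries by 0.533 log2 units or more, above the 0.214 that a change of scaling gives any gene. Exchanging these scalings would thus not remove the ranges. The members were picked because they were called variable, so wide ranges were built in. This comparison therefore cannot decide whether scaling contributes to the calls, which stays open. Handling time, dissociation, the RNA composition that sets replicate 4 apart (small nuclear RNA of 51290 TPM against 72003 to 84848 TPM) and differences between animals stay open, and no biological explanation was tested.

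Mitochondrial genes with nuclear copies differed between libraries, with an SD of log2 CPM of 4.93 for mt-Co2 and 1.55 for mt-Co3, whose call ended without replicate 4 (edgeR adjusted p = 0.34). When each was summed with its copies, such as Gm28661, chosen after its values were seen, 0 of 3 family sums passed the variability test, and the SDs were 0.199 and 0.141. A candidate explanation for mt-Co2, mt-Co3 and mt-Atp6 is that reads were assigned to different copies in different libraries. It was not tested for mt-Nd4l and does not cover mt-Cytb, mt-Nd2 and mt-Atp8, which were called too and share 0% to 3.09% of their sequence. It leaves open why mt-Co2 and mt-Co3 also passed with kallisto-layout counts (edgeR adjusted p = 0.024 and 0.0065).

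Markers of other spleen cells differed between libraries, although cells were selected on CD19. A lower share of B cells in some libraries, with the other types in fixed proportions, would raise all other types alike. The macrophage minus T cell deviation was 1.32 in replicate 1 and -1.09 in replicate 4. Its interval excluded 0 in these 2 of 4 libraries. That interval resampled genes within a library as if they were independent and held no error between libraries, so it cannot decide against this explanation. Carry-over of a single cell type would also lower the share of B cells. In replicate 2 macrophage and T cell genes were both low, at -0.82 and -1.06, with an interval of their difference that covers 0. There 6 of 8 other cell type lists lay farthest below the B lineage list, so a higher share of B cells in replicate 2 stays open. By scaled counts all 14 tested macrophage genes were highest in replicate 1 (13 by TPM, where Spic was not) and 9 of 11 T cell genes in replicate 4, although genes of a cell type are not independent, which is consistent with carry-over of different cells in different libraries. Spic and Hmox1, the most abundant macrophage genes, averaged 3.99 and 3.54 TPM and the T cell gene Lck 9.93 TPM, 1 of 20 macrophage and 2 of 19 T cell genes stand in another list, selection on CD19 would remove both types, and differences between animals stay open, with no biological explanation tested.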

How the results depend on the processing

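Differences between lists kept their sign under the alternatives run, while the order of the leading V genes changed in the kallisto-layout table, where Uty and Kdm5d lay above 1 TPM. Genes above 1 TPM ranged from 11188 to 12496. Genes more variable than the trend numbered 528 with no count filter, 69 without robust estimation and 159 without genes that share sequence, an alternative chosen after seeing the data, in which all 128 remaining calls of the main result were kept. They numbered 129 to 202 with a replicate left out, the lowest without replicate 4. Scaling on the spike-in total called 259, of which 208 were shared, and the kallisto-layout counts 212, of which 109 were shared. Of named genes, 30 lost their call without robust estimation and 13 with kallisto-layout counts. The B lineage minus T cell difference was 6.75 with a pseudocount of 1, which moved 11 of 14 list differences by over 1 SD. Members of at least 0.1 TPM alone moved 7, among them B lineage minus erythroid from 9.19 to 3.86 and follicular minus immature from 8.47 to 5.64, and means over members moved 6, with 7.67 for the erythroid list. The Igkc share was 61.8% by expected counts and 60.4% in the kallisto-layout table. The median CV of V gene shares was 11.4% in the kallisto-layout table, 15.2% with V genes of at least 0.1%, also chosen after seeing the data, and 8.82% to 10.14% with a replicate left out. The leading transcript was shared by 81.7% of genes by estimated counts. Transcripts differing between tables numbered 8874 to 12050 with a replicate left out, the lowest without replicate 1. The spike-in spread minus gene spread was -0.0259 to -0.00668 with a replicate left out, so without replicate 4 it lost most of its size. The lowest replicate correlation was 0.982 with a pseudocount of 0.1, 0.972 over genes of at least 1 TPM and 0.923 by Spearman. The cause of these changes was not tested. Levels in TPM depend on the table, since 192 of 260 named genes moved by over 1 SD in the kallisto-layout table, and 219 moved and 31 did not when small and mitochondrial RNA was left out, which multiplied TPM by 1.86 to 1.92. No pairing of samples between groups was possible because there is 1 group. At this depth Cenpf, at 0.253 TPM, rested on 12 to 48 counts per library.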

Other observations

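Some genes were high in a single library. Tspan10 (chromosome 11, 120442644 to 120446950), a tetraspanin gene, had 458 counts in replicate 2 against 16, 15 and 0 in replicates 1, 3 and 4 (edgeR adjusted p = 1.4e-08). The chemokine gene Ccl28 had 205 counts in replicate 2 against 5, 1 and 0 (edgeR adjusted p = 5.8e-07). Both share none of their sequence with other genes. Iqcn was not high in a single library alone, with 6.82, 18.7, 20.8 and 34.8 TPM in replicates 1 to 4 (edgeR adjusted p = 6.9e-08). Its 5.10-fold range was 1.86-fold without replicate 1 and 3.05-fold without replicate 4.

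Both Nnt entries, annotated at overlapping positions on chromosome 13, varied in the gene table and not in the kallisto-layout table. The entry that covers the longer span stood at 2.55, 8.08, 7.86 and 7.39 TPM in replicates 1 to 4, and the other at 5.21, 0.43, 0 and 0.8 TPM. Their edgeR adjusted p-values were 0.0001 and 3.5e-07 with the gene table, and 0.869 and 0.821 with kallisto-layout counts. The entries moved in opposite directions between replicate 1 and the others, so neither alone shows a change of Nnt as a whole.

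The marginal zone list ranked above all matched random lists in dispersion although 0 of its 12 members passed over all genes tested and 4 did adjusted over the list alone. Of small nuclear RNA genes 24 of 33 tested passed, and of small nucleolar RNA genes 21 of 63, without a test of enrichment. Small nuclear RNA summed to 51290 TPM in replicate 4 against 72003 to 84848 TPM in the others, and small nucleolar RNA to 22647 against 28560 to 30384 TPM. Ribosomal protein genes had 3 of 96, mitochondrial genes 7 of 15 and replication histone genes 7 of 62.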
